A study of Hoolock leuconedys and Symphalangus syndactylus and Hylobates moloch with 22 samples.

How the data were processed

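Chromatin immunoprecipitation with sequencing (ChIP-seq) was made in lymphoblastoid cell lines (lymphocytes made to grow without limit by Epstein-Barr virus) of 4 gibbon species, per the labels. The species were the eastern hoolock (Hoolock leuconedys, HLE), the siamang (Symphalangus syndactylus, SSY), the silvery gibbon (Hylobates moloch, HMO) and the northern white-cheeked gibbon (Nomascus leucogenys, NLE), each from a different genus. Per the labels' protocols, the cells were fixed with formaldehyde, the chromatin was pulled down with antibodies against CENP-A, CENP-B or CENP-C, and libraries were built without size selection. The labels name 22 samples, 7 of them input samples with no antibody. Samples were grouped by species and antibody from their titles. Each of the 12 groups of a species and a protein had 1 peak list, from 1 animal. The labels give CENP-A samples for 3 further hoolock animals, whose peaks were not analysed here, and the input samples have no list that was analysed here.

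Per the submitters' processing notes, the authors used Trimmomatic, Bowtie2 and MACS2, the usual tools for trimming reads, aligning them and calling peaks. For the 3 further hoolock animals the notes name Trimmomatic alone. Their versions, the genome build, the MACS2 settings and whether the input served as control are not given in the sources used here. The deposited lists name broad peaks in their title, so peaks are regions of variable length without a summit. For each peak the authors give a pileup (a signal, the height of the stacked fragments), a fold enrichment (a ratio of the pileup to the background MACS2 estimated) and a −log10 q-value, whose log base the lists do not write out. These values are the authors', and they were used here to describe, rank and filter peaks within a list. The lowest −log10 q-value of a list lay between 1.00 and 1.02, so weak peaks were kept. All 12 lists use the same sequence names, with chromosomes such as 1a, 7b and 22a and many scaffolds not placed on a chromosome, so the reads of all species were put on a common set of sequences. Reads of 3 of the 4 species, or of all 4, were thus aligned to another species' assembly, and sequence that diverges from it or is missing from it, as centromeric repeats often are, can lose reads. Reads from repeats that the assembly holds in fewer copies than the cells pile up on the copies that are there. Coordinates are printed as the lists give them, and the sources used here do not say whether starts count from 0 or 1.

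The number of peaks, covered length, peak length and the authors' peak values were described per list. No list held peaks that overlap each other. There was no replicate within a group, and no p-value between groups was computed, also not between proteins with the animals as blocks. Overlap was the percent of peaks of a list that share at least 1 bp with a peak of another. Chance overlap came from 1000 circular rotations of a list along each sequence (seed 1), with the length of a sequence taken as the farthest peak end in any list. Chance values of the alternatives used 100 rotations or shifts, and 20 rotations for the rule of 50% of the shorter peak. The rotations describe the lists at hand and are not a test between conditions. All peaks were compared first, and then the 1000 peaks with the highest fold enrichment per list, called the strong peaks. Percentages carry exact (Clopper-Pearson) 95% confidence intervals. These cover counting error only, and peaks are not independent of each other. Depth per library is unknown, because the lists give no read totals. The overlap code was tested on simulated lists of 20000 peaks with the peak lengths of the HLE lists and a planted share, where the largest error over 9 simulations was 0.287 percentage points. Labels of the 3 proteins were also permuted within species, a test chosen after seeing the data, to ask whether lists of the same protein share more between species than lists of different proteins.

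The rule for named peaks was set before the data were examined. Peaks of a list within 10 kb of each other were merged into regions, and the 5 regions with the highest fold enrichment were named by their highest peak. In each species, up to 5 CENP-A peaks that overlap a strong peak of both other proteins were named, in the order set by the sum of the 3 fold enrichments. The planned parts on distance to assembly gaps, sequence content (tandem repeats, the CENP-B motif, base composition) and genes at peaks, with the gene lists fixed for them, need a genome and annotation of the lists' build and were not run. Alternatives set before the data were examined used only peaks with a fold enrichment of at least 5 or a −log10 q-value of at least 10, an overlap of at least 50% of the shorter peak, only sequences of at least 1 Mb, 100 or 5000 strong peaks, and a ranking by −log10 q-value. Added after seeing the data were shifts of 100 to 500 kb in place of rotations, shares counted in the second list, the −log10 q-value ranking for position, and the analyses of peaks of a single protein, of windows of 1 Mb and of chromosome X. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.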

Results

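The series compared where 3 proteins of the centromere bind in 4 gibbon genera. CENP-A is the histone H3 variant that marks centromeric nucleosomes, CENP-B binds a short motif found in many centromeric satellites, and CENP-C is an inner kinetochore protein that binds CENP-A nucleosomes. There were 12 peak lists, 1 per species and protein, all from 1 animal per species, with 3506017 peaks in total on 3430 sequences. With a single list per group a difference between 2 lists had no replicate error to be set against, the proteins were not tested with the animals as blocks, and the library depth behind the lists is unknown. Pileup, fold enrichment and −log10 q-value are the authors' values for each peak. No gene annotation of the lists' build was used here, so peaks are given by position alone.

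The CENP-C lists differed most in length between species. HLE had 141597 CENP-C peaks against 314807 for CENP-A, and NLE had 139315 against 255710. In the other species the CENP-C list was the longer, with 368260 against 352325 peaks in SSY and 383872 against 300921 in HMO. CENP-B lists held 297233 peaks in HLE, 334828 in SSY, 267428 in HMO and 349721 in NLE. Covered length followed a similar order, from 75.7 Mb for HLE CENP-C and 80.8 Mb for NLE CENP-C to 409 Mb for SSY CENP-A. In SSY the CENP-C list had more peaks than the CENP-A list but covered less, 329 Mb.

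Most peaks were weak. The median fold enrichment of a list lay between 2.72 and 3.18 and the median peak length between 431 and 741 bp. A −log10 q-value of at least 10 was reached by 70 peaks (NLE CENP-C) to 950 peaks (HLE CENP-B) per list, at most 0.320% of a list. By this measure HLE had 822 CENP-A and 345 CENP-C peaks, SSY 822 and 607, HMO 306 and 553, and NLE 173 and 70, so the order of CENP-A and CENP-C turned in SSY. A fold enrichment of at least 5 left 1232 CENP-A and 151 CENP-C peaks in SSY, 486 and 353 in HMO, and 70 and 72 in NLE, which turned the order in all 3 of these species.

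**Figure D1:**
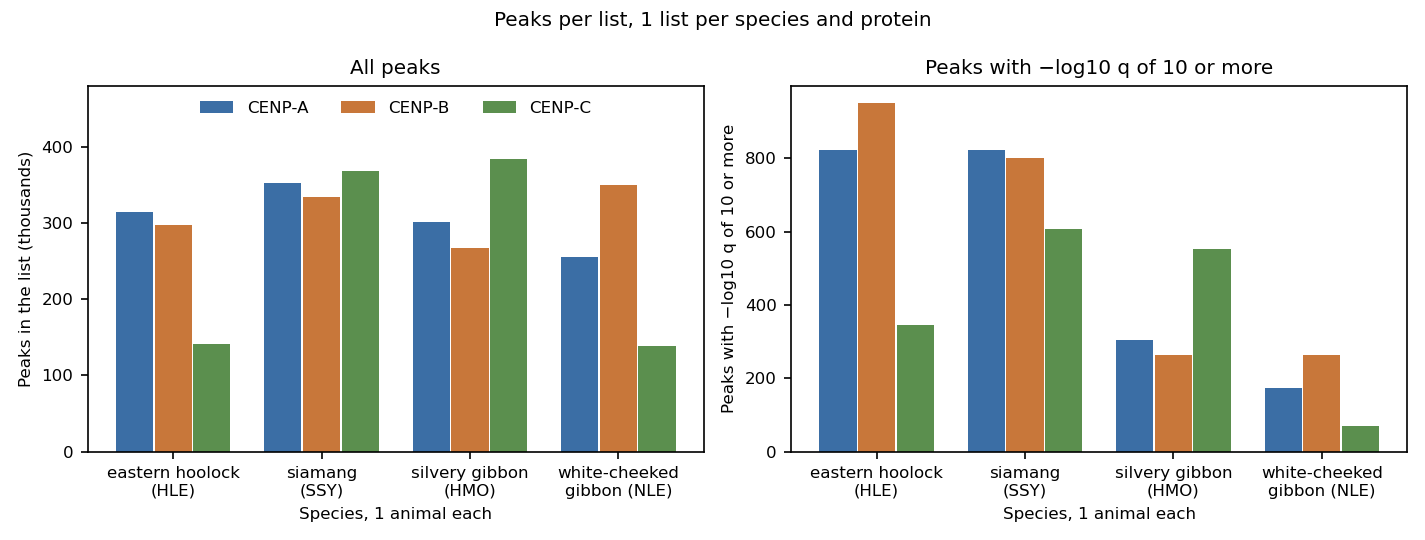
Bars give the number of peaks in each of the 12 lists (left) and of those with a −log10 q-value of at least 10 (right, peaks), by species and protein, 1 list each and therefore without error bars. CENP-C lists were the shortest in HLE (141597 peaks) and NLE (139315) and the longest in SSY (368260) and HMO (383872).

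Within each species the peaks of the 3 proteins lay at the same places more often than chance. In HLE 61.9% of CENP-A peaks overlapped a CENP-B peak, in SSY 65.8%, in HMO 46.4% and in NLE 67.3%, against 19.98%, 25.9%, 15.1% and 25.4% after rotation. The highest of 1000 rotations was below the observed share in each of the 12 pairs of lists. CENP-A peaks overlapped CENP-C peaks at 57.8% in SSY and 66.3% in HMO, and at 25.1% in HLE and 25.4% in NLE, the species with short CENP-C lists. Counted from the CENP-C list, a choice made after seeing the data, the shares were 61.3% in HLE and 48.6% in NLE, beside 62.6% in SSY and 47.9% in HMO. Over the 4 species the overlap was 60.3% ± 9.57 (SD between species, n = 4) for CENP-A with CENP-B, 43.6% ± 21.5 for CENP-A with CENP-C and 44.1% ± 22.4 for CENP-B with CENP-C. The overlap exceeded rotation 2.84-fold, 2.93-fold and 2.82-fold in this order. With only peaks of a fold enrichment of at least 5 the mean shares were 25.2%, 8.73% and 8.60%.

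Strong peaks, the 1000 with the highest fold enrichment per list, were compared with each other, which lowers both the share and chance against the full lists. Many were low in signal, with median pileups of 8.04 (NLE CENP-C) to 15.3 (HMO CENP-C), where the lowest pileup of a list was 4 to 7. Their median −log10 q-values were 2.83 (NLE CENP-C) to 7.26 (SSY CENP-B). The 1000 highest by −log10 q-value had median pileups of 13.2 (NLE CENP-C) to 72.6 (SSY CENP-C). CENP-A and CENP-B shared 32.2% (exact 95% interval 29.3 to 35.2%) of strong peaks in SSY, 22.4% (19.9 to 25.1%) in HLE, 20.3% (17.8 to 22.9%) in HMO and 11.3% (9.40 to 13.4%) in NLE. CENP-A and CENP-C shared 22% in SSY, 20.2% in HMO, 10.9% in HLE and 4.80% (3.56 to 6.31%) in NLE. CENP-B and CENP-C shared 19.8%, 21.6%, 10.0% and 3.90% in the same species. Rotation gave at most 2.20% in any of these pairs. The means over species were 21.6% ± 8.58 (SD, n = 4) for CENP-A with CENP-B, 14.5% ± 8.08 for CENP-A with CENP-C and 13.8% ± 8.35 for CENP-B with CENP-C. Ranked by −log10 q-value, the means were 67.6%, 57.7% and 55.4%, with CENP-A and CENP-B of HLE sharing 81.9%, and the mean of the rotations was also higher, 4.89 to 14.2% in the 12 pairs.

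All 3 proteins had a strong peak at 123 CENP-A peaks in SSY, 92 in HMO, 50 in HLE and 22 in NLE. By the sum of the 3 fold enrichments, the first of these in SSY was on chromosome 18 from 76444781 to 76445066, with fold enrichments of 10.2 for CENP-A, 8.01 for CENP-B and 9.54 for CENP-C. The first in HMO was on chromosome 11 from 28860772 to 28861331 (8.29, 10.1 and 7.59), in HLE on chromosome 5 from 82325628 to 82326028 (6.94, 8.08 and 7.12), and in NLE on chromosome 9 from 117813724 to 117814287 (7.04, 6.47 and 5.15). The chromosome 18, 11 and 9 sites had a peak in all 3 other species, and the chromosome 5 site in 2 of them. Of the 20 sites named by this rule, the lowest sum was 15.8, on chromosome 22a from 47111647 to 47112588 in NLE.

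Between species, peaks of the same protein that were strong by fold enrichment seldom lay at the same place. As many of these peaks had low pileups, a low share does not by itself show that binding sites differ. CENP-A peaks were shared at 5.20% ± 2.82 (SD between the 6 pairs of species), CENP-B peaks at 4.70% ± 3.23 and CENP-C peaks at 2.78% ± 2.24. HLE and SSY shared most, with 10.0% (8.21 to 12.0%) for CENP-A and 10.5% (8.67 to 12.6%) for CENP-B, but 3.00% (2.03 to 4.26%) for CENP-C, where SSY and HMO shared 6.60% (5.14 to 8.32%). HLE and NLE shared 0.6% (0.220 to 1.30%) of CENP-C peaks. Each of the 18 pairs exceeded the highest of its own rotations, which was 0.2 to 1.00%. Lists of the same protein shared about as much between species as lists of different proteins, with means of 4.23% and 4.13%. The difference was reached by 65 of the 216 ways to assign the protein labels (exact permutation test, one-sided p = 0.301). That test was chosen after seeing the data and does not show that there is no difference. Lists of the same animal shared 16.6% on average over 12 pairs. By −log10 q-value the same-protein means rose to 24.7%, 24.1% and 21.0%, and the same-animal mean to 60.2%. The mean of the rotations rose as well, to between 3.04 and 6.47% for the 18 pairs of the same protein, and the ranked peaks were longer, with a median of 828.5 against 262 bp for HLE CENP-A.

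**Figure D2:**
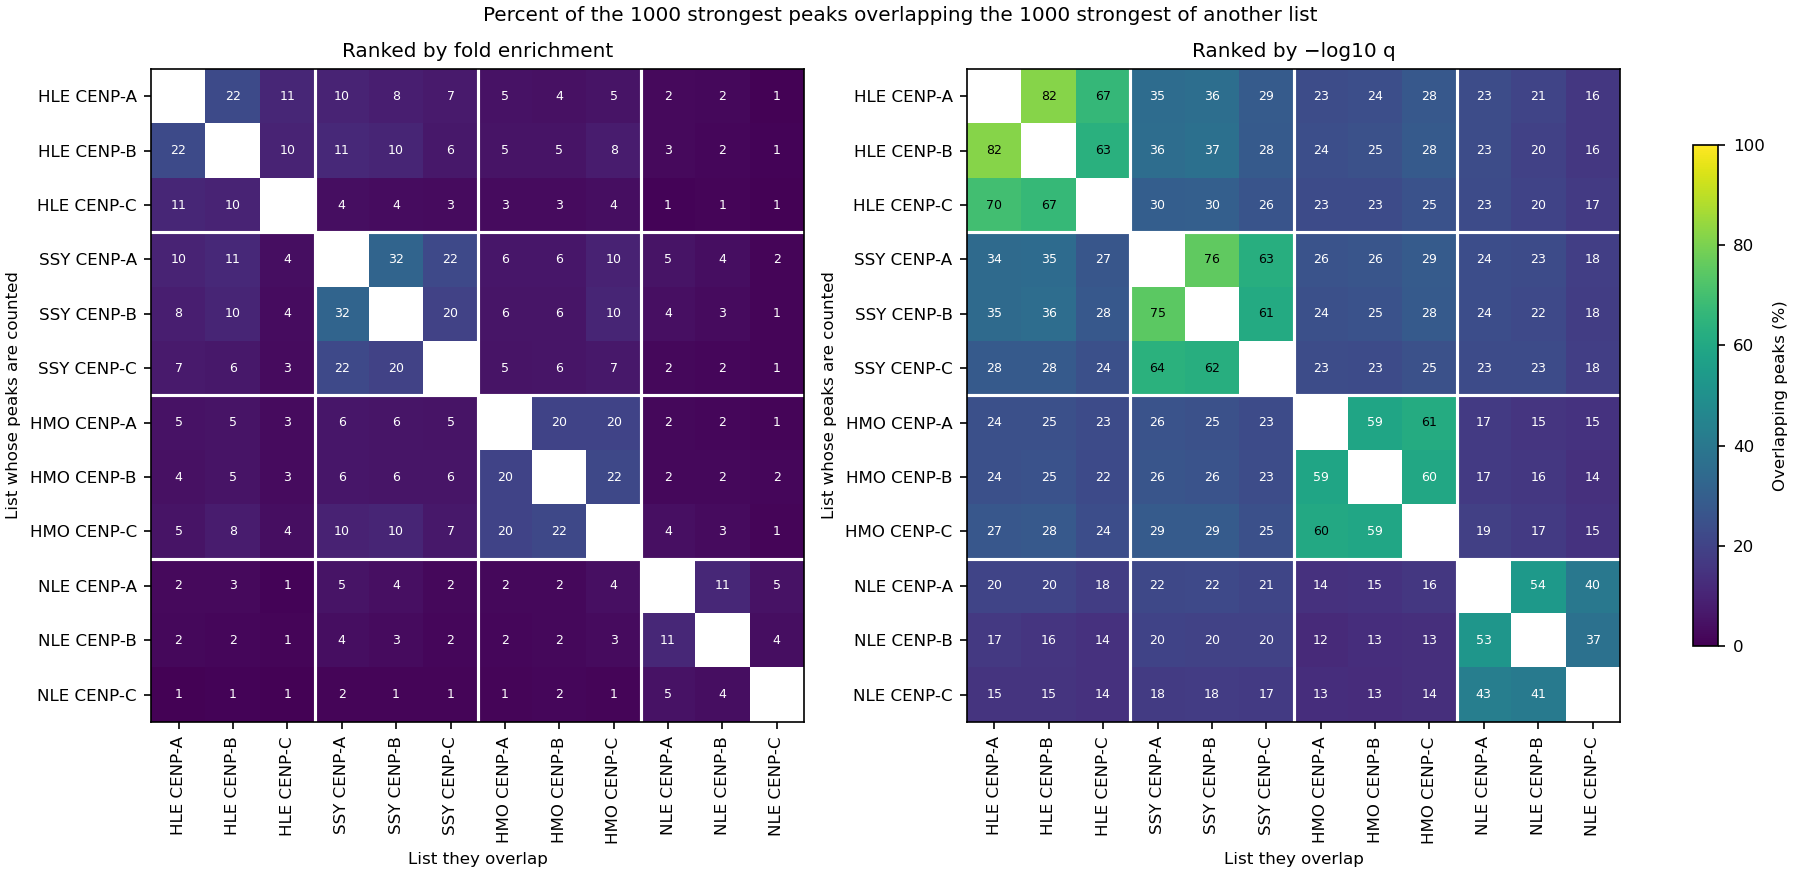
Each cell gives the percent of the 1000 strongest peaks of the list in the row that overlap one of the 1000 strongest of the list in the column, with peaks ranked by fold enrichment (left) or −log10 q-value (right), and white lines parting the 4 species. Lists of the same animal, in the blocks along the diagonal, have a mean of 16.6% on the left and 60.2% on the right, but on the left the NLE block falls to 3.90%, below the 11.4% of HLE CENP-B with SSY CENP-A.

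The peaks named for the highest fold enrichment, 5 per list, were short, with a median of 270 bp and fold enrichments from 6.17 to 11.9. Of these 60 peaks, 48 had a peak of both other proteins of the species at the same place, 36 had a peak in all 4 species and 12 were in all 12 lists. Some places were named in more than 1 list, so the 60 are not separate places, and chance shares were not computed for these counts. The peaks they met could be weak, as for HLE CENP-C on chromosome 8 at 8630658 (pileup 6.44, −log10 q-value 1.71). The highest in HLE was on chromosome 8 at 8630649 to 8630926, with a fold enrichment of 10.4 for CENP-A and 11.3 for CENP-B (8630651 to 8630888), and the same place was among the first 5 of NLE CENP-B with 7.50. The second in HLE, on chromosome 18 at 81689963 to 81690222, reached 9.49 for CENP-A and, at 81689965 to 81690232, 10.8 for CENP-B, with a peak in 1 further species. HLE CENP-C had its highest peak on chromosome 15 at 96474418 to 96474598 (9.25).

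SSY lists were led by chromosome 15 at 50960609 to 50960890 for CENP-A (10.9), chromosome 14 at 48291154 to 48291409 for CENP-B (10.7) and chromosome 18 at 76444771 to 76445061 for CENP-C (9.54). In HMO chromosome X at 21593835 to 21594064 led CENP-A (9.33), chromosome 11 at 28860714 to 28861331 led CENP-B (10.1) and chromosome 10 at 30843444 to 30843705 led CENP-C (8.01). The chromosome 11 peak was in all 12 lists and among the first 5 of all 3 HMO lists. NLE CENP-A was led by chromosome 12 at 11987884 to 11988356 (7.06) and NLE CENP-C by chromosome 2 at 80844294 to 80844537 (6.91). NLE CENP-B stood apart, since its first peak lay on an unplaced scaffold, chrUn_GL404212_1, at 1468 to 1743, with a fold enrichment of 11.9, the highest of any list, and in none of the other 11 lists.

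Strong peaks lay outside the assembled chromosomes more often than peaks at large. Between 1.95% and 2.73% of all peaks of a list were on scaffolds outside the assembled chromosomes, which held 2.67% of the known length. Some of these scaffolds carry a chromosome in their name, such as chr21_GL397648_2_random. Among the strong peaks it was 17.4% (exact 95% interval 15.1 to 19.9%) for NLE CENP-B, and 4.70% (3.47 to 6.20%, HMO CENP-B) to 10.1% (8.30 to 12.1%, SSY CENP-B) in the other 11 lists. The means over species were 7.83% ± 1.90 (SD, n = 4) for CENP-A, 9.65% ± 5.64 for CENP-B and 6.38% ± 1.07 for CENP-C. Among the 100 strongest peaks NLE CENP-B reached 48.0%, against 19.0% for NLE CENP-A and 15.0% for NLE CENP-C. In the other 9 lists it was 3 to 7%, with SSY CENP-A at 5% and HMO CENP-C at 3%, below their shares among the 1000 strongest (9.80% and 7.90%). Ranked by −log10 q-value, an alternative chosen after seeing the data, the means were 30.9%, 34.6% and 30.0%, with 58.6% for NLE CENP-B.

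Chromosome X held far fewer peaks in HMO and NLE than in HLE and SSY, a comparison made after seeing the data. Peaks per Mb on X over those on the 25 autosomes were 0.734 ± 0.00731 in HLE and 0.771 ± 0.0120 in SSY (SD between the 3 lists of an animal), but 0.162 ± 0.0277 in HMO and 0.111 ± 0.0429 in NLE. In counts, X held 11652 CENP-A peaks in HLE and 13658 in SSY, but 2379 in HMO and 1068 in NLE. The lowest autosome of HMO and NLE lists had a ratio of at least 0.627. No autosome differed between lists by more than 1.39-fold, against 9.60-fold for X.

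**Figure D3:**
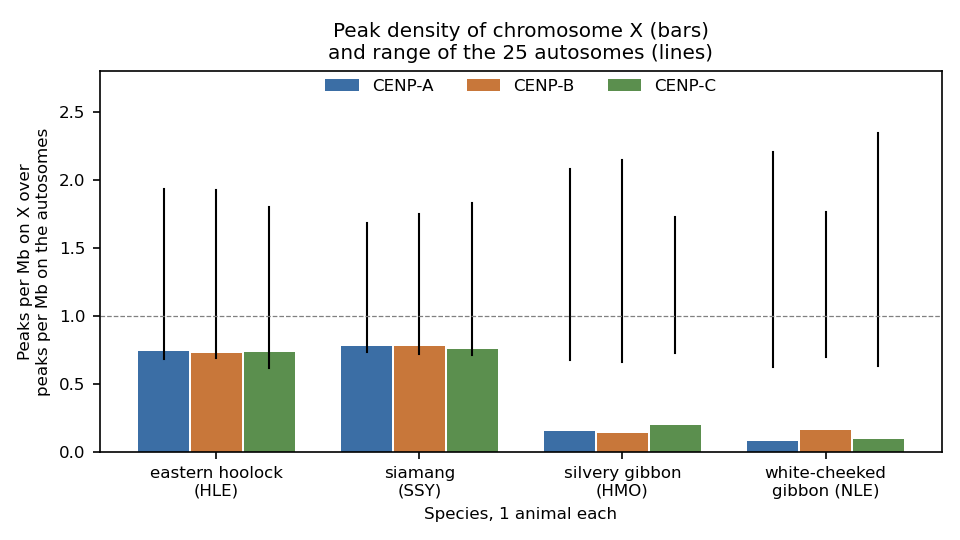
Bars give peaks per Mb on chromosome X divided by peaks per Mb on the 25 autosomes (no unit) for the 12 lists, and black lines the range of the single autosomes in the same list. In HMO and NLE all bars are at 0.194 or below, under the lowest autosome, and in HLE and SSY all are at 0.726 or above.

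Peaks with a −log10 q-value of at least 10 formed clusters, found after seeing the data. The window of 1 Mb with the most was on chromosome 6 from 26 to 27 Mb, with 229 such peaks over the 12 lists and between 11 and 29 in each list. Most lay from 26.0 to 26.2 Mb, where peaks of any strength covered 72.1 to 88.1 kb in the NLE lists, 47.7 to 50.1 kb in HLE, 43.6 to 47.2 kb in HMO and 34.7 to 40.5 kb in SSY. The second window, chromosome 16 from 22 to 23 Mb, had 123, with 10 to 15 in each list of HLE, SSY and HMO and 1 to 4 in NLE. The next windows were fullest in SSY. Chromosome 21 from 44 to 45 Mb had 13, 16 and 17 peaks in the CENP-A, CENP-B and CENP-C lists of SSY, 3 to 6 in HLE, up to 4 in NLE and up to 1 in HMO. The scaffold chr21_GL397648_2_random had 19, 18 and 24 in SSY and 0 in the other 9 lists.

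**Figure D4:**
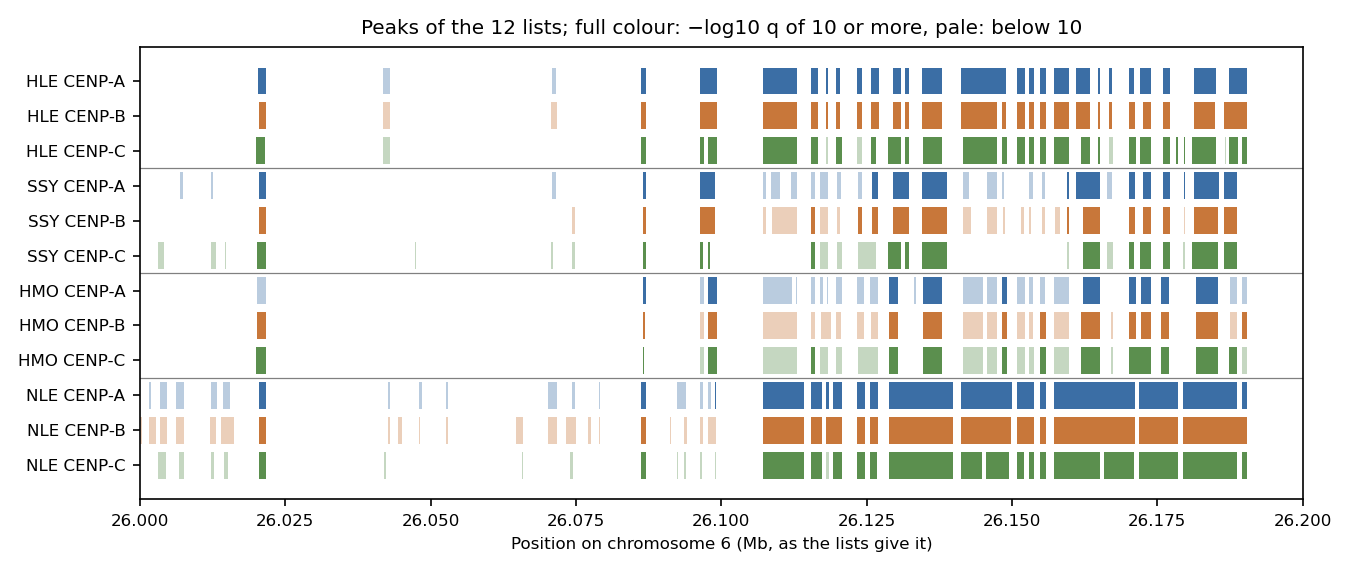
Map of chromosome 6 from 26.0 to 26.2 Mb with the peaks of the 12 lists as blocks to scale, in full colour where the −log10 q-value is at least 10 and pale below. The NLE lists cover most, with 88.1 kb for CENP-B, and SSY CENP-C has no peak between 26138813 and 26159451, where SSY CENP-A and CENP-B have weak ones.

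Among the peaks with a −log10 q-value of at least 10, most were in all 3 lists of the animal. At least 88.6% overlapped a peak of any strength of both other proteins in 10 of the 12 lists. The exceptions were SSY CENP-C with 80.4% and NLE CENP-B with 70.3%. Chance shares were not computed for these counts, and longer peaks meet others more easily. In HLE CENP-A the median length was 937 bp for peaks that met both and 206 bp for peaks that met neither. In NLE CENP-A it was 892 against 923 bp, the latter from 2 peaks. In SSY, 97 of 607 CENP-C peaks (15.98%, exact 95% interval 13.2 to 19.1%) overlapped no CENP-A or CENP-B peak. Of these, 67 were on scaffolds outside the assembled chromosomes, some of them named for chromosome 21. Such scaffolds also held 288 (47.4%) of all 607. In NLE, 57 of 263 CENP-B peaks (21.7%, 16.8 to 27.1%) overlapped none of the other proteins. These 57 were on 57 different unplaced scaffolds, with a median length of 290 bp and a median fold enrichment of 4.28. Scaffolds outside the chromosomes held 188 (71.5%) of all 263. The other 10 lists had 0 to 19 peaks that overlapped none of the other proteins. At a −log10 q-value of at least 5 the counts no longer stood apart, with 244 in HLE CENP-B and 195 in HMO CENP-C beside 200 in SSY CENP-C and 191 in NLE CENP-B, while the shares were 7.76%, 8.33%, 12.5% and 24.8%. This count was also made after seeing the data.

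**Figure D5:**
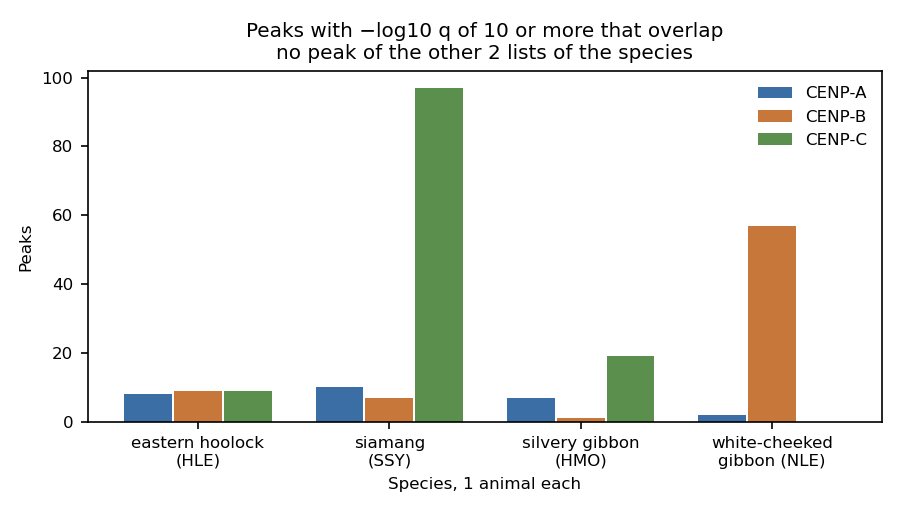
Bars count the peaks with a −log10 q-value of at least 10 that overlap no peak of the other 2 proteins of the same species, for each of the 12 lists. SSY CENP-C (97) and NLE CENP-B (57) stand above the other lists at this threshold, which have at most 19.

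Across species, peaks with a −log10 q-value of at least 10 were shared in part. In HLE 79.2% of such CENP-A peaks overlapped a peak of any strength in all 3 other species, against 27.2% after rotation. The share was 61.8% against 17.5% for SSY CENP-A, 71.9% against 22.6% for HMO CENP-A and 52.6% against 27.0% for NLE CENP-A. NLE CENP-B had the lowest share, 38.0% against 20.9%, and 36.9% of its peaks overlapped none in any other species, against 16.1% for SSY CENP-C, 15.6% for NLE CENP-A and 1.09 to 8.57% in the other 9 lists.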

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

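The ratio of peak number between proteins had opposite directions in different species, a difference that was not tested because each group has a single list. CENP-C over CENP-A was −1.15 on the log2 scale in HLE and −0.88 in NLE, but 0.064 in SSY and 0.35 in HMO. CENP-B over CENP-A was −0.083 in HLE, −0.073 in SSY and −0.17 in HMO, but 0.45 in NLE. The median pileup of the lists differed in the same direction as the number of peaks in 4 of 4 species for CENP-C and in 2 of 4 for CENP-B.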

How the results depend on the processing

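Single shares of peaks were called unmoved inside their 95% interval. Means over species or pairs were held against the mean of the single intervals' limits, which is not a 95% interval of the mean. For ratios to chance, the limits were first divided by the mean of the rotations. Numbers of peaks and ratios of them were called unmoved within 1.5 times. Small shifts of these large lists thus also appear here. The cause of the shifts was not tested, except that fewer peaks remain under a stricter threshold. Depth is unknown and no library can be left out, since each group has 1 list. The 3 proteins of a species were taken from the same animal, and a test of the proteins paired by animal was not run. Not run for want of a genome were the distance of 3 Mb to a gap, the sequence content alternatives and the gene alternatives.

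A fold enrichment of at least 5 left 781, 1325 and 180 peaks (CENP-A, CENP-B, CENP-C) in HLE, 1232, 1367 and 151 in SSY, 486, 397 and 353 in HMO, and 70, 61 and 72 in NLE. A −log10 q-value of at least 10 left 822, 950 and 345, then 822, 801 and 607, then 306, 263 and 553, and 173, 263 and 70. The log2 ratio of CENP-B over CENP-A reversed to 0.76 (fold enrichment) and 0.21 (q-value) in HLE, 0.15 (fold enrichment) in SSY and −0.20 (fold enrichment) in NLE. CENP-C over CENP-A reversed to −3.03 (fold enrichment) and −0.44 (q-value) in SSY, −0.46 (fold enrichment) in HMO and 0.041 (fold enrichment) in NLE, and moved to −2.12 (fold enrichment) in HLE.

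The mean overlaps of CENP-A with CENP-B, CENP-A with CENP-C and CENP-B with CENP-C were 25.2%, 8.73% and 8.60% at a fold enrichment of at least 5. They were 52.4%, 37.0% and 37.7% with 50% of the shorter peak, and 57.6%, 55.1% and 58.0% counted in the second list (added after seeing the data). Sequences of at least 1 Mb moved none of these 3. Over chance, the overlaps were 68.0-fold, 173-fold and 108-fold at a fold enrichment of at least 5, where chance shares are near 0. They were 3.24-fold, 3.30-fold and 3.19-fold with 50% of the shorter peak, and 2.87-fold, 2.96-fold and 2.85-fold on sequences of at least 1 Mb. With shifts of 100 to 500 kb (added after seeing the data) they were 2.03-fold, 2.07-fold and 2.01-fold.

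Strong peaks in the same 3 pairs overlapped at 15.9%, 11.1% and 10.8% with 5000 peaks and at 67.6%, 57.7% and 55.4% by q-value. With 100 peaks CENP-B and CENP-C moved to 10.8%. Between species, the q-value ranking gave 24.7% for CENP-A, 24.1% for CENP-B and 21.0% for CENP-C, and neither 5000 peaks nor 50% of the shorter peak moved a mean. Strong peaks outside the chromosomes were 16.8% for CENP-B with 100 peaks, a mean set by NLE with 48.0% beside 6 to 7% in the other species. By q-value (added) the means were 30.9%, 34.6% and 30.0% for CENP-A, CENP-B and CENP-C. CENP-C peaks of SSY without other proteins (97) numbered 200 at a −log10 q-value of at least 5 and 45 at 20, and the CENP-B peaks of NLE (57) 191 and 9. By count neither stood apart at 5, where HLE CENP-B had 244 and HMO CENP-C 195, and at 20 NLE CENP-B was close to HMO CENP-C (7). By share at 20, NLE CENP-B had 11.1% and SSY CENP-C 16.5%, beside 3.93% for HMO CENP-C. Values of single lists, pairs and windows stayed in 51 and moved in 87 cases under settings chosen before the lists were seen, and stayed in 26 and moved in 50 under those added after.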

Other observations

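The tests in this part, with the shifts, the label permutation and the counts on scaffolds and chromosome X, were chosen after the results were seen, while the ranking by −log10 q-value was set before. Several of the peaks with the highest −log10 q-values, also chosen after their values were seen, had very high pileups in at least 1 animal. In another animal they had low pileups or no called peak. On chromosome 2 at 4352491 to 4352748 the HMO lists had pileups of 580, 603 and 1455 for CENP-A, CENP-B and CENP-C, while the NLE lists had 21.8, 18.4 and 21.8 and HLE and SSY had no peak. On chromosome 11 at 32831819 to 32832014 the pileups were 616, 563 and 895 in HMO and 390, 411 and 284 in HLE, with no peak in SSY and a single one of 6.78 (CENP-B) in NLE. On chromosome 24 at 24985063 to 24985501 they were 788, 874 and 446 in NLE, 485, 496 and 304 in HLE and 170, 182 and 82.5 in SSY, with no peak in HMO. On chromosome 22a at 104529258 to 104529546 HLE had 1071, 1104 and 658, HMO 221, 158 and 199, SSY 52.9, 37.5 and 73.9, and NLE a single peak of 7.88 (CENP-B). On chromosome 6 at 26154821 to 26155810, by contrast, each animal had a peak, with pileups from 109 (SSY CENP-B) to 801 (NLE CENP-B). SSY had none for CENP-C there, and its CENP-A and CENP-B peaks were weak, with −log10 q-values of 4.60 and 2.27. A place without a called peak may still hold reads, and pileups of different lists are not on a common scale of depth. Where peaks were called, fold enrichments differed less than pileups. For CENP-A on chromosome 22a they were 4.63 in HLE, 4.88 in SSY and 3.82 in HMO. For CENP-A on chromosome 2 they were 2.78 in HMO and 3.25 in NLE. A gap in pileup between animals is thus not a gap in enrichment of the same size.

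The CENP-C peaks of SSY without CENP-A or CENP-B differed from the CENP-B peaks of NLE without the others. They had a median pileup of 226 and a median fold enrichment of 2.14, against 42.5 and 4.28. Of the 54 scaffolds outside the chromosomes that held 67 of the SSY peaks, 24 held a CENP-A peak and 26 a CENP-B peak of SSY. Peak density in windows of 1 Mb ranked the windows alike in all lists, with mean Spearman correlations across 2805 windows (not independent) of 0.914 to 0.987 within and between species. Between HLE and NLE the mean rose from 0.914 to 0.968 without chromosome X, and between SSY and HMO from 0.936 to 0.983.

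Strong peaks were shared by the lists of an animal more than by the lists of a protein on average. By −log10 q-value the NLE lists shared 37.2 to 53.9%, against 14.8 to 23.8% in same-protein pairs with an NLE list. The lowest NLE share was about that of CENP-B of HLE and SSY (37.0%), a pair without NLE. By fold enrichment NLE was less clear. CENP-A and CENP-C of NLE shared 4.80%, below the 5.30% of CENP-A of SSY and NLE. Regional density of peaks over 100 kb or more does not alone account for the sharing within an animal. The share by −log10 q-value exceeded the highest of 100 shifts by at least 25.8 percentage points in all 12 pairs of lists of an animal. Shifts were not run between animals, so they do not bear on the excess over lists of a protein. Clustering within less than 100 kb was not tested by them, and on shorter scaffolds they act as rotations. Protein identity carried across species was not decided by the label permutation (a difference of 0.0375 percentage points, one-sided p = 0.343), which does not bear on sharing between proteins of an animal. Copy number or input DNA of the animal may set the strongest peaks, and so may binding of all 3 proteins at the same sites. The mean of 60.2% shared within an animal does not decide between them. In HLE CENP-A the 1000 highest by −log10 q-value had a median pileup of 62.6 and a median fold enrichment of 3.76. The whole list had 6.34 and 3.03, so the background at these peaks was high as well. Whether that background came from the input is not given, so these cannot be told apart without a peak list of the input.

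The 57 CENP-B peaks of NLE on scaffolds without CENP-A or CENP-C peaks also have several candidate explanations. DNA or background brought by the CENP-B antibody was not decided. The CENP-B lists of the other 3 species held 4 peaks on the 57 scaffolds, but their CENP-A and CENP-C lists held only 0 to 4 each. Reads of those species may be lost on these sequences, so background might not have shown there. DNA of another source in this library alone might be the cause, since only 3 of the scaffolds had a peak in any other list, and CENP-B binding particular to NLE would look the same. A collapsed repeat in this animal's genome also stays open, since the 0 CENP-A and CENP-C peaks of NLE on these scaffolds follow in part from how the peaks were chosen. With 1 library these cannot be told apart.

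Chromosome X held fewer peaks in HMO and NLE. Distance of the species from the reference is argued against only as the sole cause, and only if the reference is a Nomascus assembly. The sequence names look like those of one, and HMO, at a mean ratio of 0.162, lay by NLE and not by HLE and SSY. The build is not given, and the X copies of the HMO animal are unknown. A part played by distance was therefore not excluded. The number of X copies in the cells of the animal is a candidate explanation, with the lowest ratio of HLE and SSY at 3.75 times the highest of HMO and NLE. How peak number follows copy number was not measured, so the size of this gap does not test it. The NLE lists were not alike, however, at 0.0810 for CENP-A, 0.160 for CENP-B and 0.0923 for CENP-C. The labels used here give no sex, and a species difference in binding on X was not tested, so these cannot be told apart with 1 animal per species.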
